A study of Mus musculus with 463 samples.

How the data were processed

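RNA was measured in 16 bulk libraries (8 groups of 2) and 447 single cells (12 sorted groups, 41 numbered sets) of mouse embryonic pancreas and liver bud. Per the submitters' notes, bulk libraries came from sorted cells by poly(A) selection and single cells by Smart-seq2, and reads were aligned to GRCm38 with TopHat2 2.1.0 and counted with HTSeq 0.6.0. The annotation release and the read filters are not given in the sources used here. The deposited count tables hold integer reads for 40824 genes and 92 spike-ins. The deposited RPKM tables were checked against the counts: 0 of 327328 bulk values and 0 of 18289452 cell values lay more than 0.0051 from the RPKM computed here. The bulk RPKM pool the 2 libraries of a group, so the tests used counts. The labels give 25 ventral E9.5 cells a growth protocol of human stem cells. They were kept as mouse cells.

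Bulk libraries held 8779418 to 24551520 reads on genes and 19004 to 21238 detected genes. Cells held a median of 1064163 reads on genes (201191 to 1738015) and 9578 genes, with a median spike-in share of 2.58% of reads. All 447 cells had at least 100000 reads and 2000 genes. No doublet caller was run. The labels do not say whether a numbered set is an embryo, a litter, a sort or a plate. Cells were summed per set, and sets of 3 or more cells were the replicates (37 sets in 11 groups), which left out 3 sets. The 4 E15.5 liver cells form 1 set and are given as values.

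Counts were filtered and scaled by TMM and tested with edgeR 4.0.16 by the quasi-likelihood F test, with Benjamini-Hochberg adjustment over 17690 genes (bulk) or 17433 genes (sets) and a threshold of 0.05. One model each covered all bulk libraries and all sets. Differences between 2 comparisons were tested as contrasts of the same model. Gene lists written before the data were examined were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with a correlation estimated from the residuals. Standard errors (SE) are the size of the log2 fold change divided by the square root of its F statistic. They thus restate the test. The rule for named genes took, per comparison, up to 8 genes per direction with an average log2 CPM of 3 or more and groups that did not overlap (not applied to differences between comparisons), up to 4 members of each list, and a fixed set of 11 genes. Unnamed gene models, ribosomal and mitochondrial genes were left out, and this filter was widened after RP23-8J15.3 was seen. Levels against groups with no reads are bounds from 3 counts over the group, which cover counting error only. Coordinates are those of GENCODE vM21 by Ensembl identifier.

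Cells were clustered with scanpy 1.11.5 and leidenalg 0.10.2 from 2000 variable genes, 20 components and 15 neighbours at resolution 1. A cluster took the marker list, written beforehand, with the largest share of members enriched 2-fold and at 10 CPM or more in 50% of its cells. It stayed unnamed with fewer than 3 such members, or where another list had more members among its top 10 genes. These thresholds were set after the clusters were seen. Shares have exact 95% Clopper-Pearson intervals, and a share of 0 is given instead the upper limit of 3 cells over the cells of the group.

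Alternatives were DESeq2 1.42.0, RLE scaling, no filter on low counts, a test against a 1.5-fold change, the set number as a block, sets of 5 or more cells, cells thinned to 100000 reads, other cluster resolutions and each library or set left out in turn. The methods were also tested on simulated data: of 50 genes changed 4-fold, edgeR found 70% in bulk E10.5 and 20% in Pdx1+ sets, with 6 and 0 false calls, and DESeq2 made 61 false calls in Pdx1+ sets. Python 3.11.15 and R 4.3.3 were used.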

Results

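Ventral and dorsal pancreas cells of mouse embryos were compared in 2 data sets. Bulk RNA-seq covered Pdx1-GFP progenitors at E10.5, Ngn3-GFP high and low cells at E14.5 and Insulin-RFP beta cells at E17.5, with 2 libraries in each of 8 groups and 8779418 to 24551520 reads on genes per library. Smart-seq2 covered 447 single cells of 12 sorted groups in 41 numbered sets, with a median of 1064163 reads on genes and 9578 detected genes per cell. The questions were which genes separate the ventral from the dorsal pancreas at each stage, how Ngn3-high and Pdx1-high cells differ from the low cells of each side, how Liv2-sorted ventral cells and the liver bud relate, and what changes between E9.5 and E10.5. Levels are CPM, counts scaled to the TMM-adjusted total of reads on tested genes, as mean ± SD over libraries or sets. CPM of individual cells and of the E15.5 cells used the plain total of reads on genes. Fold changes are log2 values from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The labels do not say whether a set is an embryo, a litter or a plate, so p-values of single cells measure only the spread between sets, which may be technical. Each gene call given below held when any 1 library or set was left out, unless a left-out library or set is named. Barx1, Shox2 and Lhfpl2 were not followed in this way. In GRCm38, Sim1 lies on chromosome 10 (50894754 to 50989152), Irx1 and Irx2 on chromosome 13 (71957921 to 71963723 and 72628820 to 72634198), Emb on chromosome 13 (117208536 to 117274415), Gcg on chromosome 2 (62474530 to 62483650), Sox17 on chromosome 1 (4490931 to 4497354), Pdx1 on chromosome 5 (147269959 to 147275848) and Afp on chromosome 5 (90490737 to 90508907).

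At E10.5, ventral Pdx1+ bulk libraries had far less endocrine RNA than dorsal ones. Gcg, which encodes the alpha cell hormone glucagon, stood at 21.6 ± 21.1 CPM in ventral and 2416 ± 34.1 CPM in dorsal libraries, a log2 fold change of -6.84 (SE 1.00, adjusted p = 0.00117). All 16 measured secretory granule genes fell, among them Chgb (13.0 against 308 CPM) and Ptprn2 (11.9 against 364 CPM), as did 18 of 20 endocrine progenitor genes and 11 of 12 alpha cell genes. Neurog3, the transcription factor that starts the endocrine program, fell from 89.7 ± 3.22 CPM in dorsal to 9.12 ± 2.78 in ventral cells, and Neurod1, which acts after it, from 102.5 to 4.01 CPM. Irx1 and Irx2, transcription factors found in alpha cells, had log2 fold changes of -5.73 and -5.92. Sim1, a transcription factor of the hypothalamus and of dorsal pancreas, fell to 0.948 ± 0.401 CPM against 79.2 ± 12.7. Adjusted p = 0.065 with an estimated correlation for the granule list, 0.0801 for the endocrine progenitor list and 0.0508 for the alpha cell list, so these list calls rest on the preset correlation. The cell mix differed as well: alpha cell-like cells were 10 of 27 dorsal Pdx1+ single cells (37.0%, 19.4 to 57.6%) against 0 of 59 ventral ones (up to 5.08%). That dorsal share was 0 to 100% by set, 4 of 21 without set 3 and 10 of 17 (58.8%) without set 2. Within progenitor-like cells Gcg was at 28.1 against 28.7 CPM and did not pass. Cells rich in Gcg form the alpha cell-like class, so low Gcg here was partly set by the clustering.

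Pancreatic progenitor genes were also lower on the ventral side at E10.5, in smaller steps. Pdx1, which marks the sorted cells, stood at 106 ± 8.96 CPM against 240.0 ± 6.01 (log2 fold change -1.18, SE 0.09, adjusted p = 4.88e-08), and Ptf1a, Nkx6-1, Mnx1 and Cpa1 had log2 fold changes of -1.63, -2.22, -2.09 and -1.57. Of the 15 measured progenitor genes, 9 fell and 3 rose over all genes tested, and 10 fell and 3 rose adjusted over the list alone. Gata6, a factor of early foregut endoderm, was 1 of those that rose, with a log2 fold change of 1.16. The progenitor list had adjusted p = 0.251 with an estimated correlation. The cell mix moved with these genes: progenitor-like cells made up 17 of 27 dorsal (63.0%, 42.4 to 80.6%) but 18 of 59 ventral Pdx1+ single cells (30.5%, 19.2 to 43.9%). The dorsal share ran from 0 to 100% by set and was 7 of 17 (41.2%) without set 2. Within that class Pdx1 (262.5 against 229.5 CPM), Ptf1a (112 against 86.9) and Nkx6-1 (31.3 against 22.9) were not lower in ventral cells and did not pass. The class was named by a list that holds these genes. Similar levels within it were thus partly set by the naming and cannot weigh the role of the cell mix.

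Ventral E10.5 libraries held more RNA of hepatobiliary genes, along with RNA typical of other tissues. Sox17, a factor of the extrahepatic biliary primordium, rose to 128 ± 5.26 CPM against 0.211 ± 0.156 (log2 fold change 9.21, SE 0.79, adjusted p = 1.4e-05). The fetal liver protein Afp reached 1431 ± 245 against 51.2 ± 16.9 CPM, and Itih2, Hhex and Fgg had log2 fold changes of 5.66, 2.91 and 2.56. Reln, which encodes a secreted glycoprotein, rose from 3.26 to 320.8 CPM. Of 20 hepatoblast genes 12 rose and 2 fell, Rbp4 among the latter (log2 fold change -1.29), with adjusted p = 0.251 with an estimated correlation. Cardiac muscle genes were higher too: Myh6 stood at 619 ± 202 against 3.10 ± 3.95 CPM and Tnnt2 at 147 ± 58.7 against 1.12 ± 1.30. Of 15 mesenchyme genes 7 rose, as did 3 of 8 immune and 3 of 10 erythroid genes, with none falling and adjusted p = 0.251, 0.251 and 0.314 with an estimated correlation. These counts rest on each library. The mesenchyme calls of Col1a1, Lum and Pdgfra ended without dorsal library 1 (adjusted p = 0.0597, 0.0544 and 0.0512) or 2 (0.0716, 0.0639 and 0.08). Without dorsal library 2 the calls of C1qa (adjusted p = 0.181), Fcer1g (0.107), Tyrobp (0.0995), Hba-a1 (0.102) and Hbb-y (0.0668) ended. Without dorsal library 1 those of C1qa (0.0648), Tyrobp (0.0563), Hba-a1 (0.22) and Hbb-y (0.144) ended, without ventral library 1 Fcer1g (0.0878), Hba-a1 (0.169) and Hbb-y (0.161), and without ventral library 2 Hba-a1 (0.077). The mesenchyme gene Postn rose from 2.19 to 62.7 CPM (adjusted p = 0.00521), a call that ended without dorsal library 2 (adjusted p = 0.0559).

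Some cell cycle, signalling and glycolysis genes also differed between the sides at E10.5, though these lists lost their calls with an estimated correlation. Of 16 G2M phase genes 13 rose in ventral cells and none fell, with Ccnb2 and Aurka at log2 fold changes of 0.57 and 0.55, but adjusted p = 0.134 with an estimated correlation. Of 14 BMP pathway genes 9 rose and 2 fell: the ligand gene Bmp2 had a log2 fold change of 3.62, the pathway inhibitor Smad7 1.37 and Bmp7 -0.51. Notch pathway genes fell in 6 of 16 cases, Dll3, which encodes a ligand, by 4.03 on the log2 scale. Pgk1, which encodes a glycolytic enzyme, rose from 480.2 to 1122 CPM, and 8 of 13 glycolysis and hypoxia genes rose. With an estimated correlation, adjusted p = 0.164 for the BMP list and 0.251 for the Notch and the glycolysis lists. In total 4374 of 17690 genes passed, 1810 higher and 2564 lower in ventral cells. DESeq2 gave 3836 genes, and edgeR gave 2605 without dorsal library 2 and 1816 against a 1.5-fold change.

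**Figure D1:**
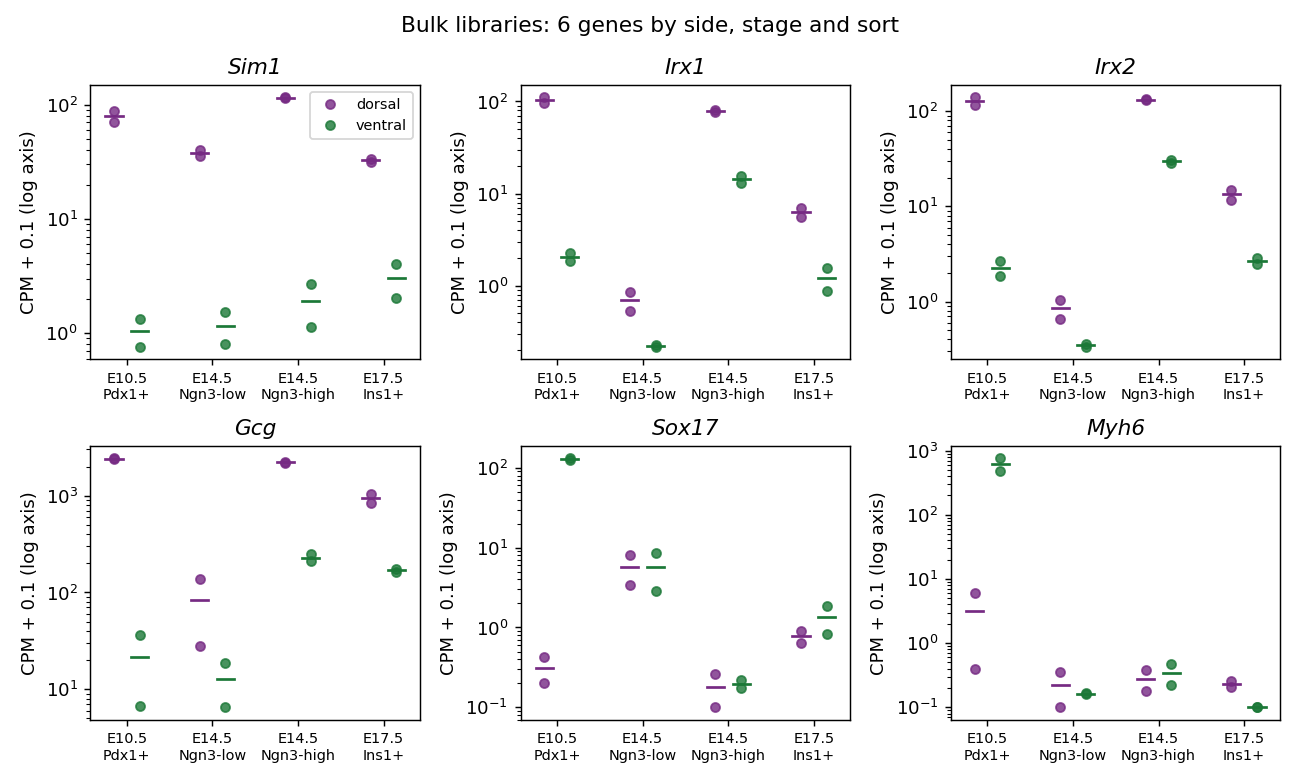
CPM of Sim1, Irx1, Irx2, Gcg, Sox17 and Myh6 in the 16 bulk libraries, on a log axis after 0.1 CPM was added, with points for libraries, lines for group means, dorsal in purple and ventral in green. Sim1 is lower in ventral than in dorsal libraries at every stage, from 0.948 against 79.2 CPM at E10.5 to 2.94 against 32.5 CPM at E17.5.

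In Ngn3-high cells at E14.5, Sim1, Irx1 and Irx2 were again lower on the ventral side. Sim1 stood at 1.82 ± 1.10 against 114.7 ± 1.58 CPM (SE 0.31 on the log2 scale, adjusted p = 1.52e-06), and Irx1 and Irx2 had log2 fold changes of -2.47 (SE 0.15) and -2.17 (SE 0.13). Of 12 alpha cell genes 4 fell and none rose, and the list call held with adjusted p = 0.0497 with an estimated correlation. Digestive enzyme genes of acinar cells were lower as well: Ctrb1 stood at 8.39 against 34.7 CPM, Pnliprp1 at 8.25 against 30.5 and Cpa1 at 13.4 against 37.4. Of 20 acinar genes 4 fell, with adjusted p = 0.147 with an estimated correlation. Other genes of Ngn3-low cells moved with them: 62 genes outside the acinar list that mark Ngn3-low cells had a median log2 fold change of -0.71, against -0.81 for the acinar list. Pdx1 (487 against 458 CPM), Neurog3 (953 against 902) and Ins1 (440.3 against 536) did not pass. Gcg, at 229 ± 26.7 against 2205 ± 47.0 CPM, did not pass either (SE 0.82, adjusted p = 0.261). The fit shares the spread of a gene over all 16 libraries, and Gcg stood at 27.8 and 137.8 CPM in the dorsal Ngn3-low libraries.

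Of 17690 genes, 95 passed in Ngn3-high cells, 11 higher and 84 lower on the ventral side, and DESeq2 gave 141. With the library number as a block more genes passed, as given below. The count rested on each library: it was 24 without dorsal library 1, 29 without dorsal library 2, 32 without ventral library 1 and 36 without ventral library 2, 10 against a 1.5-fold change and 295 with no filter on low counts. Among the higher genes, the neural transcription factor gene Sox11 had a log2 fold change of 0.80 (adjusted p = 0.00257), which ended without dorsal library 1 (adjusted p = 0.0548) or 2 (adjusted p = 0.0587).

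In Ngn3-low cells 3 of 17690 genes passed between the sides, Sim1 with the smallest adjusted p. Sim1 stood at 1.07 ± 0.502 CPM in ventral and 37.9 ± 3.20 in dorsal libraries (log2 fold change -5.12, SE 0.34, adjusted p = 6.16e-05). Pdx1 (153 against 159 CPM), Sox9 (491 against 506) and Nkx6-1 (205 against 224), genes of multipotent and ductal progenitors, did not pass. Besides Sim1, only the homeobox genes Barx1, with no reads in ventral cells, and Shox2 (2.63 against 0.217 CPM) passed, both chosen here after their values were seen. None of 12 alpha cell genes passed over all genes and 5 were lower adjusted over the list alone, and the list had adjusted p = 0.0613 with an estimated correlation. DESeq2 gave 13 genes. More genes also passed with the library number as a block, as given below. The count of 3 rose to 16 without dorsal library 1, 13 without dorsal library 2 and 8 without ventral library 2, and to 137 with no filter on low counts.

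By E17.5, ventral and dorsal beta cells differed in 5 of 17690 genes. Irx2 fell to 2.58 ± 0.266 against 13.3 ± 2.20 CPM (log2 fold change -2.33, SE 0.20, adjusted p = 4.65e-05), Sim1 to 2.94 ± 1.44 against 32.5 ± 1.48 (-3.52, SE 0.31, adjusted p = 0.000638) and Irx1 to 1.12 against 6.23 CPM (-2.52, SE 0.27). The insulin genes did not pass, with Ins1 at 28600 ± 3861 against 26610 ± 3455 CPM, nor did Pdx1 (572 against 528). Of 12 alpha cell genes 2 fell, and 5 adjusted over the list alone, and the list call held with adjusted p = 0.0252 with an estimated correlation. Gcg stood at 169 ± 9.30 against 946 ± 139.8 CPM without passing (log2 fold change -2.49, SE 0.80, adjusted p = 1.0). Gip, which encodes an incretin hormone, rose (log2 fold change 0.89, adjusted p = 0.0195) and the kinase gene Wnk3 fell (-0.73, adjusted p = 0.0342). Both calls ended without any 1 of the 4 libraries, with adjusted p from 0.0818 to 0.419 for Gip and 0.105 to 0.419 for Wnk3. The count was 3 without dorsal library 2 and 3 without ventral library 1, and DESeq2 gave 10. It was 3 against a 1.5-fold change and 94 with no filter on low counts. The libraries of a side varied more than in any other bulk group (chi-square per gene 20.86 dorsal and 29.08 ventral). Part of this went with the library number: Nkx6-1 stood at 286.7 and 311.4 CPM in dorsal and ventral library 1, and 569.4 and 615.7 in library 2. The test takes this spread as error, so the low count does not show that the sides are alike. The count with the number as a block is given below. On simulated data of this comparison, with 200 changed genes, edgeR found 62% of those changed 2-fold and 82% of those changed 4-fold. It made 14 false calls there.

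The ventral to dorsal difference itself was not the same in E10.5 Pdx1-GFP and E17.5 Insulin-RFP cells for 2251 genes, 1530 upward and 721 downward. Stage and sort change together here, and the E10.5 sides also differ in cell mix, so their parts cannot be told apart. The granule genes moved upward in 16 of 16 cases (adjusted p = 0.049 with an estimated correlation), Ptprn2 by 5.05 (SE 0.17) and Chgb by 4.83 (SE 0.29) on the log2 scale. Neurod1 moved by 4.58, Pdx1 by 1.29 and Irx2 by 3.58, and Sim1, Irx1 and Irx2 were lower in ventral cells at both stages. Reln moved by -6.40 and the cardiac gene Myl7 by -6.84. Hepatoblast genes moved downward in 5 of 20 cases and upward in 2, with adjusted p = 0.316 with an estimated correlation. DESeq2 gave 2135 genes, and the edgeR count was 1427 without dorsal E10.5 library 2 and 966 against a 1.5-fold change.

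Ngn3-high cells differed from Ngn3-low cells in endocrine and cell cycle genes on both sides. Chgb, a granule protein gene, rose to 6647 ± 383 against 8.01 ± 2.57 CPM in dorsal cells (SE 0.28 on the log2 scale, adjusted p = 2.55e-12) and to 10180 against 13.0 CPM in ventral cells. Ins2 rose from 1.28 to 997 CPM in dorsal and from 1.41 to 776 CPM in ventral cells, and Neurog3 had log2 fold changes of 2.86 and 3.02. Sox9, which marks bipotent trunk cells, had log2 fold changes of -2.76 in dorsal and -2.75 in ventral cells, and Cpa1 of -5.01 and -6.12. All 16 G2M phase genes fell on both sides, Mki67 from 682 to 49.7 CPM in dorsal cells, and all 16 S phase genes fell. Both calls held, with adjusted p = 0.0419 (dorsal) and 0.0494 (ventral) with an estimated correlation. All 16 granule genes rose on both sides (adjusted p = 0.0734 and 0.0747 with an estimated correlation), as did 19 and 18 of 20 beta cell genes (0.0731 and 0.0747). Markers of other cell types moved with the low gate: all 10 endothelial genes, such as Kdr (126 against 1.93 CPM in dorsal cells), and 6 of 8 immune genes were lower in Ngn3-high cells, with adjusted p from 0.428 to 0.528 with an estimated correlation.

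In all, 10845 genes passed between dorsal and 10941 between ventral high and low cells of 17690 tested, and DESeq2 gave 10059 and 10254. Against a 1.5-fold change 6580 and 6718 passed. The difference between sides changed with the gate for 5 genes, all lower, while 62 other markers of Ngn3-low cells had a median log2 fold change of -0.71 between the Ngn3-high sides: the acinar genes Pnliprp1 (-1.64, adjusted p = 0.0145) and Cpa1 (-1.11, adjusted p = 0.0336), Stk32b (-1.93, adjusted p = 0.0297), and, chosen here after their values were seen, Wnk3 (-1.35, adjusted p = 0.0145) and Itpr1 (adjusted p = 0.0476). All 5 calls ended without dorsal Ngn3-high library 1 or 2, with adjusted p of 0.12 and 0.0909 for Pnliprp1, 0.185 and 0.194 for Cpa1, 0.236 and 0.067 for Stk32b, 0.0515 and 0.067 for Wnk3, and 0.343 and 0.194 for Itpr1. The count was 0 without either dorsal Ngn3-high library, 3 without either ventral Ngn3-high library, 10 without dorsal Ngn3-low library 1, 1 without dorsal Ngn3-low library 2 and 10 without ventral Ngn3-low library 2. DESeq2 gave 32, and edgeR gave 0 against a 1.5-fold change and 146 with no filter on low counts. The larger count with the library number as a block is given below.

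Single cells fell into 10 clusters, of which 5 were named from marker lists. Shares pool the cells of a sorted group, with 95% intervals that cover counting error only, and the clusters were built from the same genes as the fold changes. Alpha cell-like cells made up 39 of 40 dorsal Pdx1-low cells (97.5%, 86.8 to 99.9%) and 10 of 27 dorsal Pdx1+ cells (37.0%, 19.4 to 57.6%), against 0 of 39 ventral Pdx1-low cells, which allows a share of up to 7.69%, and 0 of 59 ventral Pdx1+ cells, up to 5.08%. Pancreatic progenitor-like cells made up 27 of 28 dorsal (96.4%, 81.7 to 99.9%) and 37 of 39 ventral Pdx1-high cells (94.9%, 82.7 to 99.4%), and 17 of 27 dorsal (63.0%) against 18 of 59 ventral Pdx1+ cells (30.5%). Hepatoblast-like cells were 23 of 23 liver bud cells, 9 of 54 ventral Pdx1-low Liv2+ cells (16.7%, 7.92 to 29.3%) and 0 of 59 Liv2- cells, up to 5.08%. Of 59 ventral Pdx1+ cells 6 were hepatoblast-like (10.2%, 3.82 to 20.8%) and 7 mesenchyme-like (11.9%, 4.91 to 22.9%). At resolution 1 no class was named for 34 of 39 ventral Pdx1-low cells (87.2%), 59 of 59 Liv2- cells, 45 of 54 Liv2+ cells (83.3%) and 31 of 31 dorsal E9.5 cells. At resolution 2 a small extrahepatic biliary-like class was named, with 5 of 39 ventral Pdx1-low cells (12.8%, 4.30 to 27.4%) and 6 of 59 Liv2- cells (10.2%, 3.82 to 20.8%). It was named by 3 of 11 list members, 0 of them among its top 10 genes. Sox17, on the same list, was at 10 CPM or more in 100% of the cells of clusters 2 and 3 at resolution 1. Both clusters stayed unnamed under the naming rule, so unnamed cells need not lack biliary genes. Some shares rest on single sets: the Liv2- biliary-like share was 0 of 18 without set 1. The ventral Pdx1+ mesenchyme-like share was 7 of 26 (26.9%) without set 1 and 1 of 37 (2.70%) without set 2, and the hepatoblast-like share 4 of 26 (15.4%) without set 1. In dorsal Pdx1+ cells the alpha cell-like share was 10 of 17 (58.8%) without set 2 and 4 of 21 without set 3, and the progenitor-like share 7 of 17 (41.2%) without set 2.

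**Figure D2:**
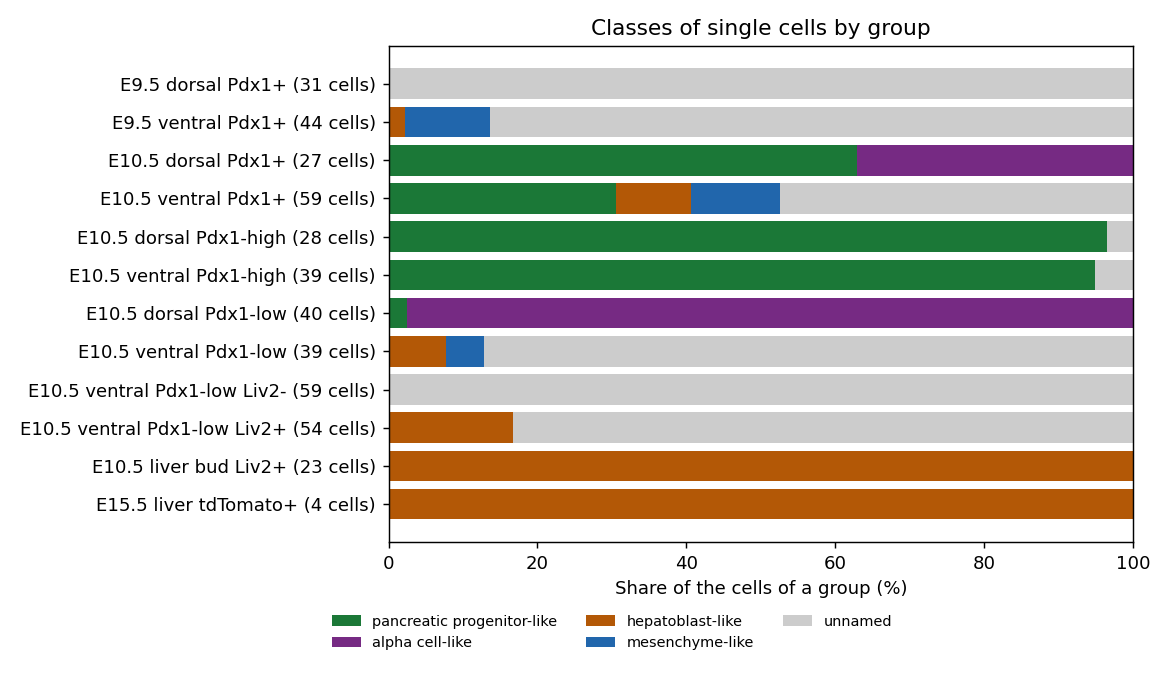
Percent of cells per named class in the 12 sorted groups, as stacked bars from 0 to 100, with unnamed clusters in their own colour. Alpha cell-like cells fill 97.5% of the dorsal Pdx1-low bar and none of the ventral Pdx1-low bar.

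In single cells of the Pdx1+ sort at E10.5, the endocrine genes were again lower on the ventral side. Neurod1 had no reads in 3 ventral sets against 223 ± 209 CPM in 3 dorsal sets, at least 2926-fold lower with a floor of 3 counts over the group (adjusted p = 1.9e-07). This bound covers counting error only, not the spread between sets. Ventral bulk libraries of the same sort did hold Neurod1 reads, with a smaller fold. Slc38a5, an amino acid transporter of alpha cells, stood at 1.60 against 9293 CPM (log2 fold change -12.25, SE 1.55), Pax6 at 0.408 against 202 and Irx2 at 0.223 against 96.7. Of 18 endocrine progenitor genes 6 fell, of 12 alpha cell genes 5 and of 16 granule genes 7, and these list calls held (adjusted p = 8.09e-07, 0.00289 and 0.00444 with an estimated correlation). Hepatoblast genes rose in 2 of 20 cases, and in 8 adjusted over the list alone (adjusted p = 0.0105 with an estimated correlation). Kitl, a growth factor gene, rose from 1.62 ± 2.64 to 115 ± 36.3 CPM (log2 fold change 6.05, adjusted p = 0.00655), a call that ended without dorsal set 3 (adjusted p = 0.0586). Afp (1809 ± 777 against 74.4 ± 58.0 CPM, adjusted p = 0.0728) and Sox17 (114 ± 103 against 1.60 ± 2.76, adjusted p = 0.0792) did not pass.

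Of 17433 genes 70 passed in Pdx1+ cells, 10 higher and 60 lower on the ventral side, and DESeq2 gave 350. The dorsal sets held 0 to 100% alpha cell-like cells, and dorsal set 3 held Pdx1, the gene of its sort, at only 3.63 CPM (Gcg at 38660), against 181 and 258 CPM in the other dorsal sets. The count was 140 without dorsal set 2, 24 without dorsal set 3, 23 without ventral set 1, 23 without ventral set 2 and 33 without ventral set 3. It was 230.0 with cells thinned to 100000 reads, 46 with no filter on low counts and 29 with sets of 5 or more cells. Bulk and single-cell fold changes of this comparison had a Pearson correlation of 0.566 and a Spearman correlation of 0.511 across 15808 genes, which are not independent replicates. All 70 genes had the same sign in bulk, and 69 of them passed in both.

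Pdx1-low cells differed between the sides in endocrine genes and in some hepatobiliary genes. Dorsal Pdx1-low cells carried Gcg at 40750 ± 9665 CPM in 6 sets against 32.5 ± 35.0 in 5 ventral sets (log2 fold change -10.28, SE 1.87, adjusted p = 0.000203), and Pyy, another islet hormone gene, at 3768 against 11.0 CPM. All 16 granule genes and 16 of 18 endocrine progenitor genes fell in ventral cells, with adjusted p = 0.00628 and 5.66e-06 with an estimated correlation. Ventral Pdx1-low cells carried Sox17 at 416 ± 61.3 against 0.0726 ± 0.127 CPM (log2 fold change 12.12, SE 1.55, adjusted p = 1.87e-06), Hhex at 396 against 0.958, Itih2 at 1113 against 6.47 and Afp at 2750 ± 2381 against 168 ± 174. Of 20 hepatoblast genes 8 rose and 2 fell, and of 11 extrahepatic biliary genes 7 rose and 2 fell, with adjusted p = 0.343 and 0.228 with an estimated correlation. Fgfr2, the receptor of a mesenchymal growth signal, had a log2 fold change of 5.11 and its target Etv4 5.02. The proliferation gene Top2a rose from 26.0 to 689.5 CPM. Of 16 G2M phase genes 15 rose, of 16 S phase genes 13 and of 13 FGF pathway genes 7, with adjusted p = 0.0929, 0.087 and 0.087 with an estimated correlation. The collagen gene Col1a1, at 252 ± 563 against 0.847 CPM, was carried by few cells: its log2 fold change of 8.27 turned to -3.09 without the mesenchyme-like cells and to -6.38 without ventral set 6. In total 4347 of 17433 genes passed, 2420 higher and 1927 lower in ventral cells, and DESeq2 gave 4907. The larger direction turned with the scaling: RLE size factors gave 2121 higher and 2279 lower, and DESeq2 2393 and 2514.

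In Pdx1-high cells the genes of the progenitor class did not pass between the sides. Pdx1 stood at 246 ± 54.4 CPM in 5 ventral and 219 ± 47.4 in 5 dorsal sets, Sox9 at 999 against 853, Ptf1a at 99.2 against 76.5 and Gcg at 38.1 against 36.6, none of which passed. Sim1 was lower in ventral cells (0.714 ± 1.36 against 41.2 ± 5.47 CPM, adjusted p = 0.0186), a call that ended without ventral set 1 (adjusted p = 0.0646) or 4 (adjusted p = 0.056) and without the high-spike-in sets 1 and 4 of both gates (adjusted p = 0.167). Emb, which encodes a cell adhesion protein, was higher (965 ± 332 against 327 ± 115 CPM, log2 fold change 1.56, SE 0.29, adjusted p = 0.0429). That call ended without dorsal set 2 (adjusted p = 0.0506), 5 (0.103) or 6 (0.211) and without ventral set 1 (0.088), 2 (0.108) or 4 (0.0958), without sets 1 and 4 of both gates (0.107), with RLE size factors (0.0569), with no filter on low counts (0.11) and with sets of 5 or more cells (0.101). Of 17433 genes 3 passed, the third being Lhfpl2 (adjusted p = 0.046), chosen here after its value was seen, and DESeq2 gave 274. The count was 5 without dorsal set 1 or 4, 1 without dorsal set 6 or ventral set 1, 2 or 4, and 14 without sets 1 and 4 of both gates. The difference between sides in Pdx1-high cells was itself apart from that in Pdx1-low cells for 1957 genes, 865 upward and 1092 downward: Gcg differed by 10.35 (SE 2.13, adjusted p = 0.00258), Itih2 by -6.02 and Etv4 by -5.05 on the log2 scale, and DESeq2 gave 2669.

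Within pancreatic progenitor-like cells alone, in 7 ventral and 7 dorsal sets and with the sort gate in the model, Sim1 and Emb passed between the sides. The class joins 2 clusters that the sides fill unequally: of progenitor-like Pdx1-high cells, 25 dorsal and 14 ventral cells lay in cluster 1, and 2 dorsal and 23 ventral cells in cluster 8. Sim1 stood at 0.569 ± 1.16 against 46.1 ± 20.2 CPM (log2 fold change -6.36, SE 0.87, adjusted p = 0.0074) and Emb at 894.5 ± 210 against 343 ± 97.7 CPM (1.40, SE 0.19, adjusted p = 0.0074). Pdx1 (262.5 against 229.5 CPM), Sox9 (1009 against 860), Ptf1a (112 against 86.9) and Gcg (28.1 against 28.7) did not pass. Pdx1, Sox9 and Ptf1a are on the list that named the class, so their similar levels within it were partly set by the naming. The gene model RP23-8J15.3, outside the naming rule and named after its value was seen, also passed (2773 against 5614 CPM, adjusted p = 0.0119), but not without dorsal Pdx1-high set 2 (adjusted p = 0.0523), dorsal Pdx1+ set 1 (0.0562) or ventral Pdx1+ set 1 (0.0583). Of 10 BMP pathway, 13 glycolysis and hypoxia and 9 endocrine progenitor genes none passed. The upward calls of the first 2 lists and the downward call of the third were lost (adjusted p = 0.102, 0.543 and 0.543 with an estimated correlation). The downward Hox call held (0.0269) but rests on 1 gene, which did not pass over all genes. These 3 genes of 11494 tested became 19 without dorsal Pdx1-high set 4, 6 without dorsal Pdx1-high set 6, 9 without ventral Pdx1-high set 1 or 2, 6 without set 5 and 5 without set 6. There were 29 with sets of 5 or more such cells, and DESeq2 gave 146.

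**Figure D3:**
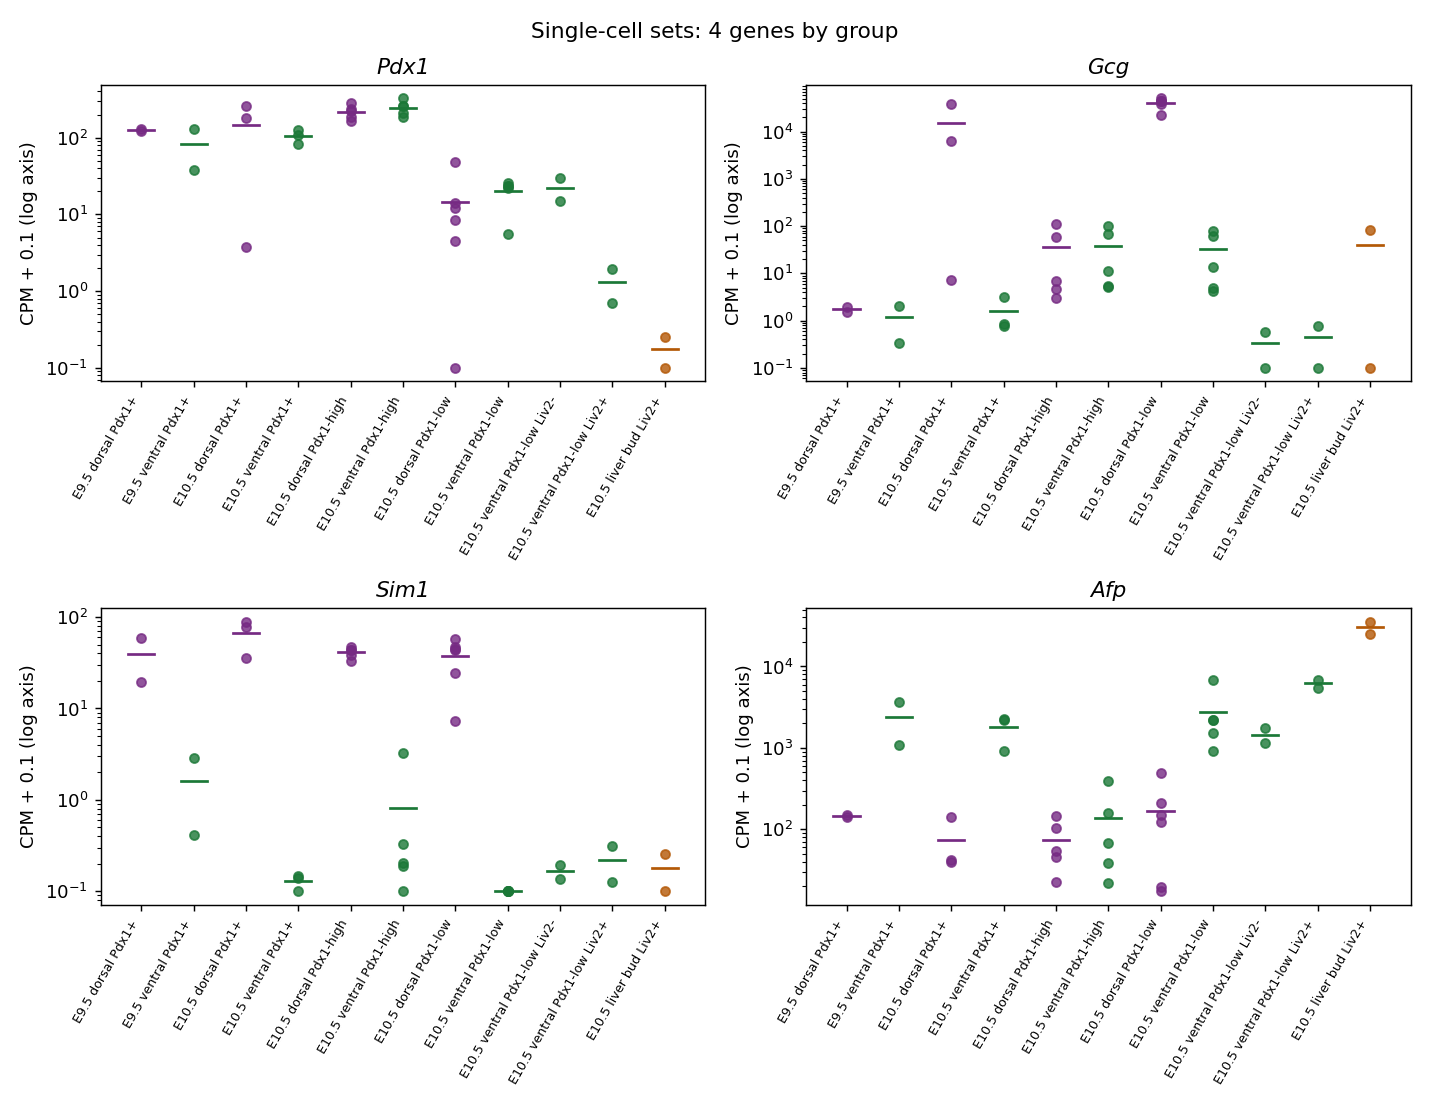
CPM of Pdx1, Gcg, Sim1 and Afp in the numbered sets of 11 sorted groups on a log axis, with points for sets, lines for group means, dorsal in purple, ventral in green and liver bud in orange. Sim1 lies at 33.3 to 47.5 CPM in dorsal Pdx1-high sets and at 0 to 3.14 CPM in ventral Pdx1-high sets.

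Dorsal Pdx1-high cells differed from dorsal Pdx1-low cells as progenitors from alpha-like cells. Pdx1 rose to 219 ± 47.4 CPM (log2 fold change 3.93, SE 0.75, adjusted p = 0.000323), Sox9 to 853 against 33.7, Ptf1a to 76.5 against 2.42 and Hes1, a Notch target, to 137 against 3.79. Gcg fell by 10.12 (SE 1.86, adjusted p = 0.000284), and Isl1, a factor of hormone cells, fell from 1072 to 0.880 CPM. Of 15 progenitor genes 8 rose (adjusted p = 0.0525 with an estimated correlation), of 13 FGF pathway genes 9 rose (0.03) and all 16 granule genes fell (0.00789). In total 4204 of 17433 genes passed, 2274 higher and 1930 lower, and DESeq2 gave 4791. Here too the larger direction turned, with 2044 higher and 2161 lower by RLE size factors and 2316 and 2475 by DESeq2.

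Ventral Pdx1-high cells differed from ventral Pdx1-low cells in progenitor against hepatobiliary genes. Ptf1a rose to 99.2 ± 34.7 against 0.222 ± 0.273 CPM (log2 fold change 8.74, SE 1.65, adjusted p = 0.00482), Nkx6-1 to 30.7 against 0.275, Kirrel2, an adhesion protein gene of islet cells, to 342 against 0.144 and Nepn to 2435 against 4.61 CPM. Sox17 fell from 416 ± 61.3 to 7.35 ± 8.51 CPM (SE 1.14, adjusted p = 0.00625), Afp from 2750 to 136 and the apolipoprotein gene Apoa2 from 101 to 0.137 CPM. Of 15 progenitor genes 7 rose (adjusted p = 0.00133 with an estimated correlation) and of 20 hepatoblast genes 4 fell and 1 rose (0.0461), with 13 falling adjusted over the list alone. The endothelial list also fell, by 2 of 8 genes (0.0461). Of 17433 genes 168 passed, 107 higher and 61 lower. The count was 105 without ventral Pdx1-low set 3 and 82 without sets 1 and 4 of both gates. DESeq2 gave 642, with 320 higher and 322 lower, so the excess of higher genes was not seen there.

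Liv2+ and Liv2- cells of the ventral Pdx1-low gate did not differ in any single gene by edgeR. Afp stood at 6200 ± 969 CPM in 2 Liv2+ sets against 1445 ± 409.9 in 2 Liv2- sets, Alb at 288 ± 74.2 against 49.6 and Pdx1 at 1.21 against 22.2, none past the threshold, and Sox17 was at 388 against 375. The hepatoblast list was higher as a whole (adjusted p = 0.000267 with an estimated correlation), with none of 20 members past over all genes and 2 adjusted over the list alone, and so was the erythroid list (0.0192). edgeR gave 0 genes (201 at an unadjusted p under 0.05) and DESeq2 gave 30. With any 1 Liv2+ or Liv2- set left out, edgeR gave at most 1. On simulated data of this comparison edgeR found 6% of 50 genes changed 4-fold and 16% of those changed 8-fold, and DESeq2 made 82 false calls.

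Lnx1, a ubiquitin ligase gene, had no reads in 2 liver bud sets against 22.2 ± 0.471 CPM in 2 ventral Liv2+ sets, at least 182.9-fold lower with a floor of 3 counts over the group (adjusted p = 7.01e-05). Grhl2, a factor of epithelial identity, had no reads against 36.4 ± 9.11 CPM (at least 312.6-fold lower, adjusted p = 0.0141), which ended without liver bud set 1 (adjusted p = 0.23) or 2 (0.437). Afp (30410 ± 7162 against 6200 ± 969 CPM), Alb (1524 against 288) and Sox17 (1.46 ± 1.35 against 388 ± 91.4, adjusted p = 0.0653) did not pass, though the hepatoblast list was higher as a whole (adjusted p = 0.0192 with an estimated correlation). Of 17433 genes 102 passed, 3 higher and 99 lower. The count was 51 without liver bud set 1, 26 without set 2, 61 without Liv2+ set 1 and 59 without Liv2+ set 2, and 181 with sets of 5 or more cells, and DESeq2 gave 487.

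At E9.5, Afp stood at 2386 ± 1835 CPM in 2 ventral against 145 ± 5.76 in 2 dorsal sets, Sox17 at 189 ± 2.85 against 49.4 ± 67.2 and Pdx1 at 83.7 ± 64.9 against 126 ± 7.31, and no gene passed by edgeR. As groups, hepatoblast genes were higher in ventral cells (adjusted p = 0.0112 with an estimated correlation), as were endothelial (0.00632) and BMP pathway genes (0.0227), and foregut and stomach genes (0.00167) and Hox genes (0.0112) were lower. Mesenchyme-like cells were 5 of 44 ventral (11.4%, 3.79 to 24.6%) and 0 of 31 dorsal E9.5 cells (up to 9.68%), with 0 of 16 ventral cells without set 1 and 5 of 28 (17.9%) without set 2. edgeR gave 0 genes (267 at an unadjusted p under 0.05) and DESeq2 gave 33.

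From E9.5 to E10.5, dorsal Pdx1+ sets gained endocrine RNA. Disp2 rose from no reads to 174 ± 187 CPM (at least 1670-fold higher with a floor of 3 counts over the group, adjusted p = 0.00455) and the keratin gene Krt8 fell from 2131 ± 4.79 to 524 ± 206 CPM (log2 fold change -2.02, SE 0.35, adjusted p = 0.00351). These calls ended without E9.5 set 1 (adjusted p = 0.155 and 0.0682) or 2 (0.302 and 0.0637). Of 16 granule genes 6 rose (adjusted p = 0.00179 with an estimated correlation), of 12 alpha cell genes 2 rose (0.000528) and of 13 glycolysis and hypoxia genes 4 fell (0.00179). Gcg, at 14990 ± 20740 against 1.62 ± 0.317 CPM, did not pass (adjusted p = 0.098): it was at 6316, 7.07 and 38660 CPM in E10.5 sets 1 to 3, and Pdx1 was at only 3.63 CPM in set 3. Alpha cell-like cells were 10 of 27 at E10.5 (37.0%, but 4 of 21 without set 3 and 10 of 17 without set 2) against 0 of 31 at E9.5 (up to 9.68%). Of 17433 genes 48 passed, 27 higher and 21 lower. The count was 107 without E10.5 set 2, 16 without E10.5 set 3, 2 without E9.5 set 1 and 1 without E9.5 set 2. It was 137 with cells thinned to 100000 reads, and DESeq2 gave 354.

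In ventral Pdx1+ cells no gene passed between E9.5 and E10.5 by edgeR. Pdx1 stood at 106 ± 21.9 CPM in 3 E10.5 sets against 83.7 ± 64.9 in 2 E9.5 sets, Ptf1a at 34.5 ± 7.61 against 8.33 ± 3.86 and Afp at 1809 against 2386. Foregut and stomach genes (adjusted p = 0.00799 with an estimated correlation), intestinal genes (0.00725) and mesothelial genes (0.00725) were lower at E10.5 as groups. edgeR gave 0 genes (379 at an unadjusted p under 0.05), at most 2 with a set left out, and DESeq2 gave 19.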

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

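The tests of Sim1 within progenitor-like cells, of Irx1 and Irx2 in dorsal Pdx1-high sets and of alpha cells at E17.5 were chosen after the result was seen. The comparisons, their tests and the gene lists of the report were chosen before the data were examined, and the cardiac list was written after Myh6, Actc1, Tnnt2, Mybpc3, Myl4 and Nkx2-5 had been seen.

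Cardiac muscle genes were higher in ventral E10.5 bulk libraries. All 20 of 20 cardiac list genes not looked at before were higher, with Myl7 at 182.9 against 2.344 CPM and Myh7 at 118.8 against 2.983. None of these 20 is in another list used here, and Slc8a1 had the highest dorsal level (9.866 CPM). Broad low transcription is argued against by the single cells: 3 or more cardiac list genes at 10 CPM were seen in 2 of 59 ventral Pdx1+ cells (3.39%, 0.413 to 11.7%) and in 2 of 27 dorsal cells (7.41%, 0.91 to 24.3%). Cardiac cells in the ventral bulk sort are a candidate source, which a Pdx1-GFP gate would remove if it were pure. The Pdx1+ single cells showed none: of these 59 ventral and 27 dorsal cells no cell had more than 3 of the list genes. Myh6 was at 0.9537, 0.2467 and 0 CPM in ventral Pdx1+ sets against 619.2 in bulk. The list was not counted in cells of other sorts, where Myh6 reached 16.08 CPM in ventral Pdx1-high set 4 and 12.67 in ventral Pdx1-low set 6. Beyond such broad low transcription, a biological difference between the buds stays open as untested.

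Sim1, Irx1 and Irx2 were lower in ventral cells at several stages. More alpha cells in the dorsal E10.5 sort are argued against for Sim1, which had a log2 fold change of -6.359 within progenitor-like cells. For Irx1 and Irx2 they are a candidate source at E10.5: the means in dorsal Pdx1-high sets, which hold few such cells, were at most 0.05632% of those in dorsal Pdx1-low sets. For Irx1 and Irx2 at E17.5, more alpha cells in the dorsal sort and a difference of the beta cells themselves cannot be told apart. Gcg had a log2 fold change of -2.487 (SE 0.80), but Slc38a5 of -0.47 and Ttr of -0.16. The 2 libraries per side are too few to decide. Dorsal E17.5 libraries held Sim1 at 31.44 and 33.53 CPM, with Gcg at only 847.4 and 1045. E10.5 dorsal Pdx1-low sets, nearly all alpha cell-like, held Sim1 at 7.116 to 57.02 CPM with Gcg at 22820 to 50290. These values argue against alpha cells with such levels as the source of Sim1. Alpha cells of E17.5 were not measured. A biological difference between the sides may be the source and stays untested.

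Acinar genes were lower in ventral Ngn3-high libraries. If more Ngn3-low cells were carried into the dorsal Ngn3-high libraries, other genes of Ngn3-low cells would be lower too. The median log2 fold change of 62 such genes outside the acinar list was -0.7108 (interquartile range -0.985 to -0.431), against -0.81 for the acinar genes. Carry-over is a candidate explanation that these values allow, and a biological difference between the sides stays open as untested.

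Other splits of the sets were drawn at random, at most 40 per comparison. For Pdx1-low cells (4347, highest other split 2093) and dorsal high against low (4204, 568), only the real split, 1 of 40, gave as many. The same held for ventral high against low (168, 5), the difference between gates (1957, 1) and progenitor-like cells (3, 0). The split with 2093 genes relabelled 10 sets, so it was close to the real one with the sides swapped. A random split is thus an unlikely source of these counts. It is not excluded, since 1 of 40 is the lowest share that 40 splits can reach. The progenitor-like count rests on only 3 genes, in a class drawn from the same data. For Pdx1-high cells (3, highest other split 8) 7 of 40 splits gave as many, so chance may be the source. For Pdx1+ cells 10 splits are too few, with 1 as large (70, highest other split 30).

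In 17 of 56 tests a single set stood apart from the others of its group. The nominal rate of 1 in 20 assumes normally distributed values, which CPM of rare genes over few cells need not follow, so 17 cannot be held against it. It fails outright for 4 of them (Sox17, Ptf1a and, in ventral Pdx1-low set 6, Neurog3 and Nkx6-1), where all other sets were at 0 and any read sets a sample apart. The 17 are given as values only. In dorsal Pdx1-high cells these were Neurog3 in set 4 (231.1 CPM), Sox17 in set 6 (0.497) and Alb in set 5 (16.77). In dorsal Pdx1-low cells they were Pdx1 (48.27), Ptf1a (14.51) and Sox9 (154.3) in set 4, and Neurog3 (82.94) and Alb (133.0) in set 3. In ventral Pdx1-high set 4 they were Neurog3 (75.55) and Ins1 (25.53). In ventral Pdx1-low cells they were Pdx1 in set 5 (5.433, against 22.09 to 25.4 elsewhere), Neurog3 (0.06243) and Nkx6-1 (1.373) in set 6, Ins1 (45.39), Ins2 (58.57) and Afp (6899) in set 3, and the median spike-in share in set 1 (10.529%).

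The ventral to dorsal difference itself differed between E17.5 and E10.5 (2251 genes), between Ngn3-high and Ngn3-low cells (5) and between Pdx1-high and Pdx1-low cells (1957). From E10.5 to E17.5 the sort changes as well, from Pdx1-GFP to Insulin-RFP cells, so stage and sort cannot be told apart.

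The 4 E15.5 liver cells of the Pdx1-Cre tdTomato group, used in no comparison, held Alb at 12760 and Afp at 41770 CPM. Ins2 stood at 86.36 and Gcg at 55.59 CPM, above the 1.489 CPM that a count of 0 allows. That limit covers counting error only. Some E10.5 sets without alpha cell-like cells held similar traces. Gcg stood at 80.98 CPM in liver bud set 2 (0 in set 1) and 77.97 in ventral Pdx1-low set 6, and Ins2 at 58.57 in ventral Pdx1-low set 3. Whether such reads come from the cells themselves was not tested.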

How the results depend on the processing

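The tests without the mesenchyme-like cells and without the high-spike-in sets 1 and 4 were chosen after the result was seen. Of 14186 values under other settings, 13280 stayed on their side of the threshold, 833 lost significance, 69 gained it and 4 reversed. A change of direction was counted only where the main fit or the other one passed. The cause was not tested unless stated.

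Gene counts moved more than 1.5 times as follows. Tested against a 1.5-fold change, a stricter test, they were 1816 (bulk E10.5, 4374 before), 10 (Ngn3-high, 95), 3 (E17.5, 5), 6580 and 6718 (dorsal and ventral Ngn3 gates, 10845 and 10941), 0 (difference between Ngn3 gates, 5) and 966 (E17.5 minus E10.5, 2251). With no filter on low counts they were 295 (Ngn3-high), 137 (Ngn3-low, 3), 94 (E17.5), 146 (difference between Ngn3 gates), 46 (Pdx1+, 70), 1 (Pdx1-high, 3) and 12 (progenitor-like, 3). DESeq2 gave 13 (Ngn3-low), 10 (E17.5), 32 (difference between Ngn3 gates), 350 (Pdx1+), 274 (Pdx1-high), 642 (ventral Pdx1 gates, 168), 30 (Liv2, 0), 487 (liver bud, 102), 33 (E9.5, 0), 354 (dorsal stages, 48), 19 (ventral stages, 0) and 146 (progenitor-like). RLE factors gave 1 (Pdx1-high). Sets of 5 or more cells gave 29 (Pdx1+), 181 (liver bud), 73 (dorsal stages) and 29 (progenitor-like). Thinned cells gave 230 (Pdx1+) and 137 (dorsal stages). Without sets 1 and 4 there were 14 (Pdx1-high), 82 (ventral Pdx1 gates) and 14 (progenitor-like).

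With the replicate block the counts were 373 (Ngn3-high), 62 (Ngn3-low), 48 (E17.5), 109 (difference between Ngn3 gates), 3867 (E17.5 minus E10.5), 7 (Pdx1-high), 378 and 137 (dorsal and ventral stages) and 15 (progenitor-like). The labels do not say that numbers pair samples. No family of 3 or more pairs had every residual correlation above 0.1. Among these families every set correlated best with its own number only in Pdx1+ cells (3 of 3), a hint from the data. With 2 libraries per group the check cannot decide for bulk. All bulk correlations were positive, 0.2863 at E10.5, 0.216 to 0.4724 at E14.5 and 0.7691 at E17.5. Spike-in reads at E17.5 were 8 and 7 in the libraries numbered 1, and 56 and 64 in those numbered 2.

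With 1 library or set left out, counts ran from 2605 to 3525 (bulk E10.5), 24 to 36 (Ngn3-high), 4 to 16 (Ngn3-low), 3 to 6 (E17.5), 9135 to 9653 and 9852 to 10218 (dorsal and ventral Ngn3 gates), 0 to 10 (their difference), 1427 to 2397 (E17.5 minus E10.5), 23 to 140 (Pdx1+), 1 to 5 (Pdx1-high), 3722 to 4399 (Pdx1-low), 3560 to 4267 and 105 to 157 (dorsal and ventral Pdx1 gates), 1558 to 2268 (their difference), 0 to 1 (Liv2), 26 to 61 (liver bud), 0 to 0 (E9.5), 1 to 107 and 0 to 2 (dorsal and ventral stages) and 2 to 19 (progenitor-like). A lone library was assumed to vary like the other groups.

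Reversed were Col1a1 (-3.089 without the mesenchyme-like cells, -6.377 without ventral Pdx1-low set 6, and up to 11.04 without dorsal Pdx1-low set 5), Col3a1 (-1.492 without ventral Pdx1-low set 6) and Apoa1 in the difference between Pdx1 gates (3.339 without sets 1 and 4). Of 598 list tests, 208 passed with the preset and 65 with an estimated correlation. The correlation of bulk and single cells rose to 0.8699 for genes with an average log2 CPM of 5 or more in both. The planned tests on RPKM were not run, since the bulk RPKM pool the libraries, and a minimum of 4000 genes removed no cell. Of 50 simulated genes changed 2-fold, edgeR found 58% in bulk E10.5 and 6% in Pdx1+ sets, with depth not varied. Thinning lowered the Pdx1-low count from 4347 to 3812 and raised that of Pdx1+ cells.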

Other observations

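No test in this part was chosen after the result was seen. The 4 E15.5 liver cells also held hepatocyte genes, with Apoa1 at 5473, Trf at 388.1, Hnf4a at 49.63, Cebpa at 28.29 and Prox1 at 57.08 CPM. All 4 fell among the hepatoblast-like cells. Ins1 stood at 41.2 CPM, a trace also seen in E10.5 ventral Pdx1-low set 3 (45.39, against at most 5.282 in the other sets of that group). No reads were found for Sox17, Ptf1a, Nkx6-1 or Krt19.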
